A study of Mus musculus with 3 samples.

How the data were processed

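The data were 3 arrays of 1 Agilent whole-genome mouse design, hybridised with Cy3-labelled cRNA made from 20 ng of total RNA, per the labels. Groups were taken from the genotype in the labels, with 1 array for WT, 1 for Dll1 -/- and 1 for Rbpj -/-. Per the file headers the 3 arrays lie on 1 slide, at 3 positions, with 1 scan time, so neither slide nor scan separates the groups.

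The authors deposited scanner files in which the processed signal is an intensity on a linear scale, background-subtracted and detrended over the array by Feature Extraction, per the file headers. Its version was 10.7 per the labels and 10.7.1.1 per the file headers. The median spot and background intensity are also given there, per the file headers. The authors' deposited series table holds log2 values. The scale and centring of that table are not given in the sources used here and were read from the values. For 100% of probes its entries were within 0.01 of the log2 processed signal plus 1 constant per array (-7.47, -7.27 and -7.14 for WT, Dll1 KO and Rbpj KO), so its values are log2 levels per array that run in the direction of the signal, with no centring per gene. Its column medians were -3.44, -3.40 and -3.28.

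Each array held 62976 spots, of which 59305 were not controls. Spots marked as outliers were left out (143 in WT, 163 in the Dll1 KO and 139 in the Rbpj KO), and 0 spots were saturated. The main values are log2 of the processed signal minus the array's 75th percentile over non-control probes, with spots of one probe averaged, which gave 55678 probes. The number of arrays, 1 per group, limits the precision. Spot SD over probes printed repeatedly had a 95th percentile of 0.19, 0.20 and 0.24 log2.

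Probes were named through their accessions and a reference gene table of assembly GRCm38.p6, which matched 27507 probes (49.4%) to 20886 genes, and the other 28171 probes were not used. The array design was built on mm9 per the file headers, so the table was used for names and no coordinates are given. A gene's level is the mean over its probes well above background on at least 1 of the 3 arrays, which left 13161 genes, 3203 of them with more than 1 probe. The mean was kept where probes disagree. Among genes with at least 2 probes measured on both arrays, probes pointed opposite ways by 1.5-fold each in 0 of 2868 genes for the Dll1 KO against WT, 12 of 2809 for the Rbpj KO against WT and 10 of 2903 between the knockouts. This check leaves out probes not well above background on both arrays, which can still enter a gene's mean. With only probes well above background on both arrays in the mean, 90, 365 and 465 genes were at least 2-fold apart, against 132, 409 and 491. Of the genes at least 2-fold apart, 76 of 132, 305 of 409 and 393 of 491 rest on 1 probe.

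The comparisons were Dll1 KO minus WT, Rbpj KO minus WT and Rbpj KO minus Dll1 KO. Differences were counted among genes with a probe well above background on both arrays, and 2-fold was the size that counted as apart. A gene well above background on 1 array of a pair has a bound only. Its bright level was set against the higher of the dim array's lowest signal well above background and the dim probe's own signal, and is given as at least N-fold. Genes in multigene families (granzymes, Klra receptors, olfactory receptors, histones, MHC genes) may share probe signal with relatives, so their single values are uncertain.

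Gene lists, 51 in all, were fixed before the data were examined, as were the main settings, the first set of alternatives and the naming rule. For a list with at least 5 measured members the median log2 difference was placed among 10000 random lists of the same size, matched on mean level in 20 bins. This was possible for 47 lists. Lists share members, such as Ccl3 and Ccl4 in the Th1, NF-kB and chemokine lists, so their shifts are not independent of each other. A list below percentile 2.5 or above 97.5 is called apart, which describes these arrays and is not a test over mice. Of the 47 lists, 14 lay above and 6 below random lists in the Dll1 KO against WT, 7 and 16 in the Rbpj KO against WT, and 10 and 21 between the knockouts.

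Named genes were Dll1, Rbpj, Cd4, Cd3e and Cd8a, and for each comparison with WT the 12 largest differences each way that were at least 1.5-fold in the same direction after normexp with quantile normalization, leaving out clone and predicted names. Between the knockouts 8 each way were taken. The 4 largest bounds each way were added, and from each list the members at least 2-fold apart, at most 4, or otherwise the 2 with the largest difference. Values for other genes are given where a count or feature is spelled out, and these were chosen after their values were seen. They are Dtx1 in the Dll1 KO against WT and Slc15a2 and Klrg1 among the genes shared by both knockouts.

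The steps were tested on simulated data for the Rbpj KO against WT over 11578 genes. Of 50 genes changed by 1.5-fold 2 were called apart at 2-fold, of 50 changed by 2.5-fold 47, and of 50 each changed by 4-fold and 8-fold all 50. Of 11353 unchanged genes 172 (1.52%) were called. The noise here too was drawn from the Dll1 KO minus WT differences at random sign, without regard to place on the array. The 1.52% is therefore not an independent rate of false calls. A list of 25 genes shifted by 0.4 log2 was recovered at 0.32, and 12 of 200 unshifted lists lay outside the central 95%. For overlap between the comparisons with WT, 3 unchanged arrays were simulated 100 times, with noise drawn from the Dll1 KO minus WT differences at random sign, so any real difference between these arrays counts as noise there and the simulation does not check the count of that comparison.

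Alternatives were normexp (offset 50) on median spot and background signals with quantile normalization, quantile normalization alone, median scaling, the deposited series values, a probe filter on all 3 arrays, no filter, the brightest probe per gene, saturated probes left out, and 1.5-fold or 3-fold as the size that counts. The design named mean spot signals for normexp, and median spot signals were used in their place. After the data were seen, scaling to E1A spike-in spots, a level of at least the 75th percentile on both arrays, only probes well above background on both arrays, and only spots in rows 193 to 384 were added. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.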

Results

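Gene expression was measured with 1-colour oligonucleotide arrays in CD4+ T cells taken 2 days after stimulation. The cells came from female C57BL/6 mice aged 8 weeks. The 3 samples, with 1 array each, were wild type (WT), a knockout of Dll1 and a knockout of Rbpj. Dll1 is a membrane-bound ligand of Notch receptors, and Rbpj is the DNA-binding protein through which activated Notch acts on transcription. The title places the question in survival signalling by Dll1 carried on activated helper T cells. With 1 array per group no difference has a replicate check, and no p-value is given. Which cells carried each deletion is not given in the sources used here.

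Signals were of similar depth on the 3 arrays. Of 55678 probes, 25941 (46.6%) were well above background in WT, 27906 (50.1%) in the Dll1 KO and 26316 (47.3%) in the Rbpj KO. The 75th percentile of the log2 processed signal, to which each array was scaled, was 7.47, 7.28 and 7.14 in the same order. Spots of one probe repeated within an array had a median SD of 0.06 log2 on each array, which covers spot error only. Against WT the median gene differed by -0.03 log2 in the Dll1 KO and by -0.07 in the Rbpj KO. After scaling to the E1A spike-in spots these medians were -0.24 and -0.82, and after scaling to each array's median they were -0.07 and -0.24. Levels below are relative to the array's 75th percentile, so they do not show the RNA content per cell.

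Probes that stood apart were unevenly spread over the array surface. In rows 1 to 192, 671 probes were at least 2-fold higher on the WT array than on both others, against 11 in rows 193 to 384. The counts were 455 against 68 for the Dll1 KO array and 495 against 277 for the Rbpj KO array. The part of the array in which a gene's probes lie is therefore given with the counts and with many of the single-gene differences.

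**Figure D1:**
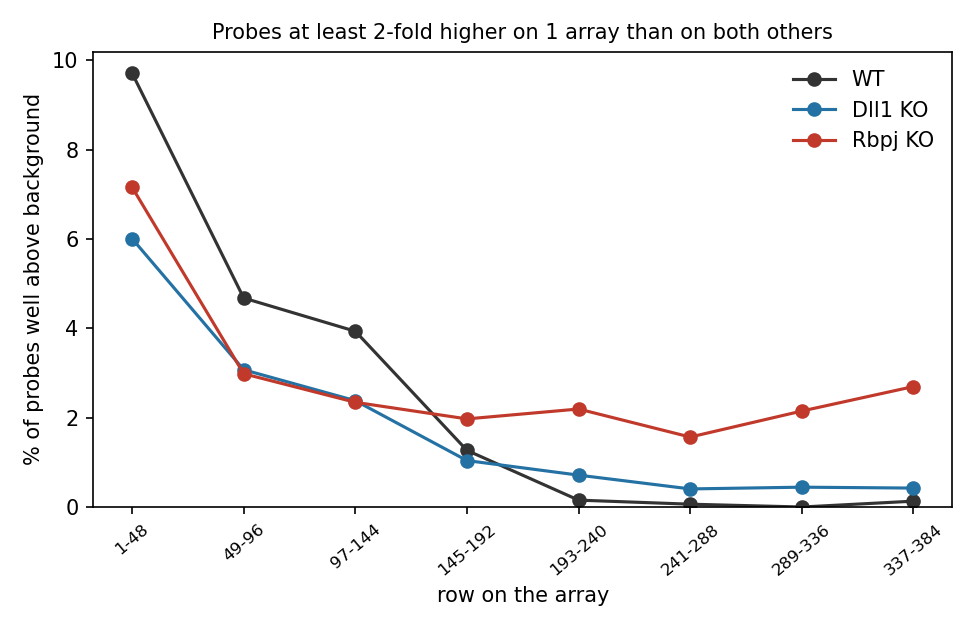
Percent of probes well above background (y axis) that were at least 2-fold higher on 1 array than on both others, in 8 blocks of 48 rows (x axis), with 1 line per array. The WT array goes from 9.71% in rows 1 to 48 to 0.13% in rows 337 to 384.

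The targeted genes were read first. Rbpj, measured by 2 probes, was 1.42-fold lower in the Rbpj KO than in WT (log2 difference -0.50, with -0.35 and -0.66 for the single probes), and stood at 0.28 above WT in the Dll1 KO. The Dll1 probe was not well above background on any array, with processed signals of 4.51 in WT, 3.60 in the Dll1 KO and 4.06 in the Rbpj KO. The lowest signals well above background on these arrays were 19.2, 13.6 and 15.8. Where these probes lie relative to the deleted sequences is not given in the sources used here, so they check neither label. Cd3e, a chain of the T cell receptor complex, was at 0.04 in the Dll1 KO, or -0.17 under spike-in scaling, and at -0.07 in the Rbpj KO. Cd4 was at -0.04 in the Dll1 KO and 0.38 in the Rbpj KO, or -0.37 there under spike-in scaling.

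The comparison of the Dll1 KO with WT asks what loss of this Notch ligand does in stimulated helper T cells. Genes of T cell activation were higher in the Dll1 KO as a group, with 30 of 34 measured members above WT and a median log2 difference of 0.26. Among them were Nr4a3, a nuclear receptor induced by T cell receptor signals, at 0.85, and Csf2, which encodes the cytokine GM-CSF, at 0.67. Cytokine genes were higher too, with 20 of 23 above WT and a median of 0.24, including Il21, a cytokine of follicular helper and Th17 cells, at 0.85. Interferon-stimulated genes were lower, with 32 of 35 below WT and a median of -0.19, led by the peptide transporter gene Tap1 at -0.56. The interferon-inducible chemokine gene Cxcl10 went the other way at 0.68.

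Genes that control cell death hardly differed as groups. The median over 24 anti-apoptotic and survival genes was 0.02 in the Dll1 KO, at percentile 90.9 of 10000 random lists of the same size and level, and that over 30 pro-apoptotic genes was 0.00, at percentile 76.7. Under spike-in scaling both medians would be lower by 0.21. The largest differences among survival genes were Bcl2l2, a relative of Bcl2, at 0.53 and the kinase gene Pim3 at -0.46. Among death genes they were Pmaip1, a BH3-only protein, at 0.42 and the caspase gene Casp4 at 0.35. Notch and Rbpj targets had a median of 0.05 over 8 genes, at percentile 88.0, and the Notch target Dtx1 was at -0.01. The DNA replication and S phase list had a median of 0.01 and the mitosis list one of -0.02, both inside the range of random lists.

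Several helper subset lists lay above random lists in the Dll1 KO, while the follicular helper list stayed inside, with a median of 0.05. Th2 genes had a median of 0.24 with 12 of 13 above WT, led by Il13 at 0.65 and Il9 at 0.62. The Th17 list had a median of 0.14 with 8 of 11 above WT. Inhibitors of T cell receptor signalling had a median of 0.12, with Rgs16 at 0.51 and Spry2 at -0.66. Regulatory T cell genes had a median of 0.12, with Klrg1, an inhibitory lectin receptor, at 1.06. Under spike-in scaling the medians of the activation, cytokine and Th2 lists stayed positive at 0.05, 0.02 and 0.03. Those of the Th17, inhibitor and regulatory lists became negative at -0.08, -0.09 and -0.10. Places among random lists are the same by construction, since this scaling shifts all genes of an array alike. Naive and quiescence genes were lower with a median of -0.16, and ribosomal protein genes with one of -0.14, with 27 of 28 below WT.

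Markers of NK cells and macrophages differed as well, while the B cell, dendritic cell, CD8 T cell, neutrophil and stromal lists stayed inside the random range. NK cell markers had a median of 0.54 over 9 measured genes, with Tyrobp, an adaptor of NK and myeloid receptors, at 1.11. The macrophage and monocyte list, which shares Tyrobp, had a median of 0.41 over 8 genes. Both stayed above 0 under spike-in scaling, at 0.33 and 0.19. S100a8 and S100a9 were lower, at -1.34 and -1.14, within a neutrophil and mast cell list whose median was -0.05. S100a8 was dim in the Dll1 KO, at a level of -3.27, and after normexp with quantile normalization the differences were -0.45 and -0.74.

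Few single genes stood apart. Of 11811 genes measured on both arrays, 44 were at least 2-fold higher and 88 at least 2-fold lower in the Dll1 KO (1.12% in all), while 95.8% were within 1.5-fold. Among the 4021 genes with the highest signals, 1 was 2-fold higher and 0 were lower. The largest higher genes by the naming rule included Slc15a2, a peptide transporter, at 4.11-fold, Dnah8, an axonemal dynein chain, at 4.06-fold, Fgd2, an exchange factor for Cdc42, at 3.46-fold, and Glo1, which detoxifies methylglyoxal, at 2.46-fold. Of the 3 probes for Dnah8 each read between 1.90 and 2.20 log2 higher. In rows 1 to 192 lay Eml5, a microtubule-associated gene, at 4.34-fold and Sag, a visual arrestin, at 3.84-fold higher. The killer cell protease gene Gzmc was 2.30-fold higher, though probes for granzyme genes can pick up related transcripts. Dnase1l2, a secreted DNase, was 8.25-fold lower. The other 11 of the largest lower genes had their probes in rows 1 to 192, among them the germ cell gene Tex14 at 6.14-fold, the keratin gene Krt42 at 5.58-fold and Cbs, which starts transsulfuration, at 4.64-fold lower. After normexp with quantile normalization these were 1.93-fold, 1.63-fold and 1.60-fold, and Dnase1l2 3.54-fold lower. Fbxo44, Trank1, Cyp3a11 and Fgf23, also among the largest lower genes, rest on a dim probe. By their probe well above background on both arrays they were at 0.60, 0.14, -0.27 and -0.46 log2. Genes measured on 1 array of the pair gave bounds, with 74 at least 2-fold higher and 164 at least 2-fold lower. The largest were Olfr1311, an olfactory receptor gene, at least 13.9-fold lower, and the vasopressin receptor gene Avpr1a, at least 8.15-fold higher, both in rows 1 to 192.

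The count of 132 genes was 17 of 6827 when only spots in rows 193 to 384 were used, where 12 were higher and 5 lower, so the excess of lower genes was not seen there, and 11 after normexp correction with quantile normalization. Using those rows alone ended the calls for regulatory T cell genes (percentile 90.5) and naive genes (9.40), a stricter level filter that for Th17 genes (95.9), and without a filter on dim probes the macrophage list had a median of -0.21.

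The comparison of the Rbpj KO with WT asks what loss of the shared Notch effector does. Effector cytokine genes were lower in the Rbpj KO, led by Il4, the signature Th2 cytokine, at 6.23-fold, Ifng at 2.44-fold, Csf2 at 2.42-fold and the T cell growth factor gene Il2 at 2.28-fold lower. Across the cytokine list 14 of 19 genes were below WT, 7 of them at least 2-fold, with a median of -0.41. The Th2 list as a whole stayed inside the random range, with a median of 0.11 and 6 of 11 genes above WT, a median of -0.06 under median scaling and -0.64 under spike-in scaling. Il17a, the defining Th17 cytokine, was 3.74-fold higher. The Notch target Dtx1, which encodes a ubiquitin ligase of the pathway, was 6.01-fold lower. Genes of regulatory T cells were higher, with the lineage factor gene Foxp3 at 2.37-fold and the Helios gene Ikzf2 at 3.01-fold.

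Over 8 measured Notch and Rbpj targets the median was -0.41, at percentile 0.37 of random lists, with 2 genes at least 2-fold lower. The other besides Dtx1 was the survival gene Bcl2, at 2.45-fold lower. The anti-apoptotic list as a whole had a median of 0.00 with 12 of 24 genes above WT and 12 below, at percentile 97.4, and the pro-apoptotic list had one of -0.06 over 30 genes, at percentile 69.2. Casp4, an inflammatory caspase, was 2.02-fold higher by both of its probes. The ligand gene Dll4 was at -0.51 and the receptor gene Notch2 at -0.31. The Notch target list was no longer apart when dim probes were kept, with a median of 0.00.

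**Figure D2:**
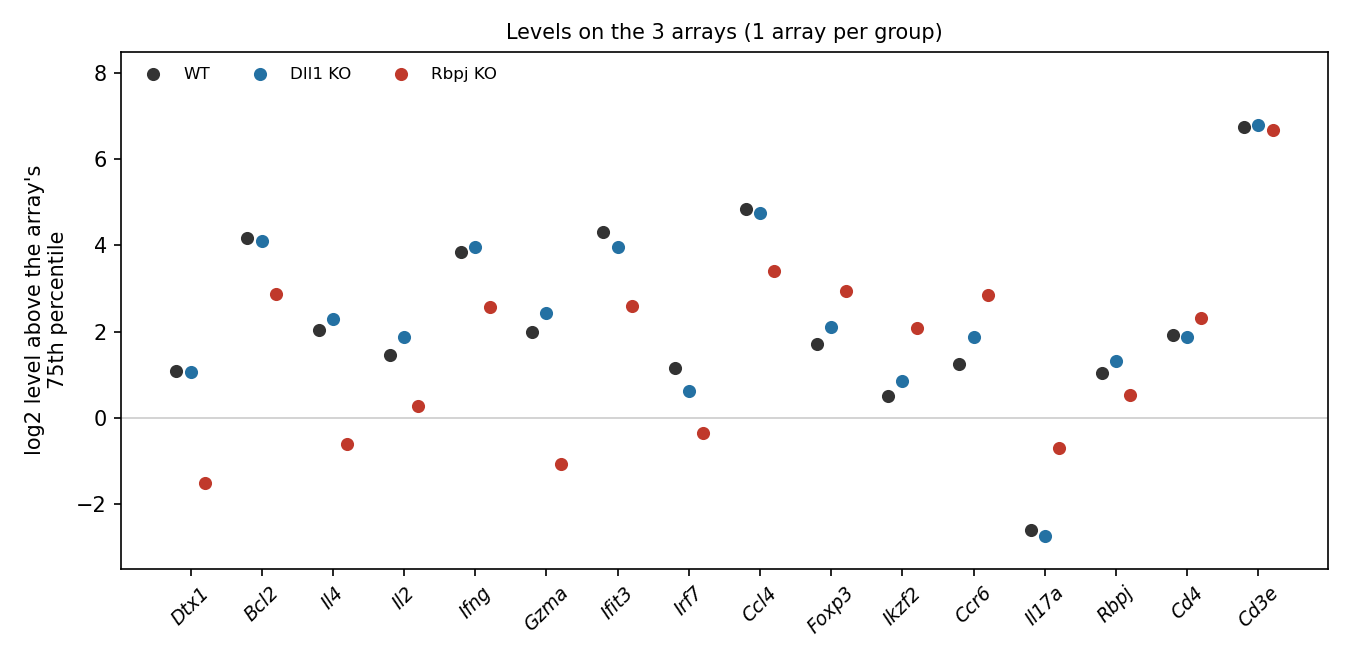
Log2 level relative to the array's 75th percentile (y axis) of 16 genes (x axis), with 1 point per array and 1 array per group. Against WT the Rbpj KO is at -2.59 for Dtx1 and -2.64 for Il4, and at 1.25 for Foxp3 and 1.59 for Ikzf2.

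Interferon and chemokine genes were lower as groups. Interferon-stimulated genes had a median of -0.67 with 33 of 35 below WT and 8 at least 2-fold lower, including the antiviral genes Ifit3 at -1.71 and Ifit1 at -1.58 and the transcription factor gene Irf7 at -1.51. Chemokine genes had a median of -0.73 with 10 of 10 below WT. Ccl9 was 2.73-fold, Ccl4 2.68-fold, Cxcl1 2.25-fold and Ccl3 2.17-fold lower, of which Ccl3 and Ccl4 are also members of the Th1 list.

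Genes of cell division and growth were lower by smaller amounts across most of each list. Of 30 DNA replication and S phase genes 29 were below WT, with a median of -0.45, and the nuclease gene Fen1 and the ribonucleotide reductase gene Rrm1 were both at -0.70. Of 25 mitosis genes 23 were below WT, with a median of -0.39, including the spindle factor Tpx2 at -0.83 and topoisomerase Top2a at -0.70. Ribosome biogenesis and MYC target genes had a median of -0.32 with 28 of 30 below WT, led by Nop56 at -0.60 and Dkc1 at -0.59, which work in modification of ribosomal RNA. T cell activation genes as a group stood at percentile 50.7, with a median of -0.10. The IL-2 and STAT5 response list had a median of -0.38, including the cytokine gene Lif at -1.22 and the signalling inhibitor Socs1 at -1.21.

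Helper subset lists moved apart from each other. Th1 genes were lower with a median of -0.33 and 13 of 17 below WT, including Eomes, a T-box factor of effector and memory cells, at 2.33-fold. Regulatory T cell genes had a median of 0.41 with 13 of 16 above WT, but Entpd1, the ectonucleotidase CD39, was 2.32-fold lower. Th17 genes had a median of 0.36 with 9 of 11 above WT, including the chemokine receptor gene Ccr6 at 1.58. Follicular helper genes had a median of 0.33 with 15 of 15 above WT, led by the transcription factor gene Ascl2 at 2.07-fold. Under spike-in scaling the medians of the regulatory, Th17 and follicular lists became negative, at -0.33, -0.38 and -0.41. This scaling shifts all genes of an array alike, so a list's place among random lists cannot change.

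Markers of several other cell types were lower in the same array. The CD8 T cell list had a median of -0.57 over 5 genes, with Cd8a at -0.76 as a mean of 2 probes and -1.29 by the one well above background on both arrays. The dendritic cell list had a median of -0.53 over 11 genes, although Ciita, the activator of MHC class II genes, was 3.12-fold higher. B cell and plasma cell markers had a median of -0.43 over 16 genes, with the joining chain gene Jchain, its probe in rows 1 to 192, 4.34-fold higher. NK cell markers had a median of -0.24 over 9 genes, at percentile 4.67 and so inside the random range, yet Gzma, a granule protease of killer cells, was 8.38-fold lower. The dendritic list rested on the filter, with a median of 0.06 when dim probes were kept.

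**Figure D3:**
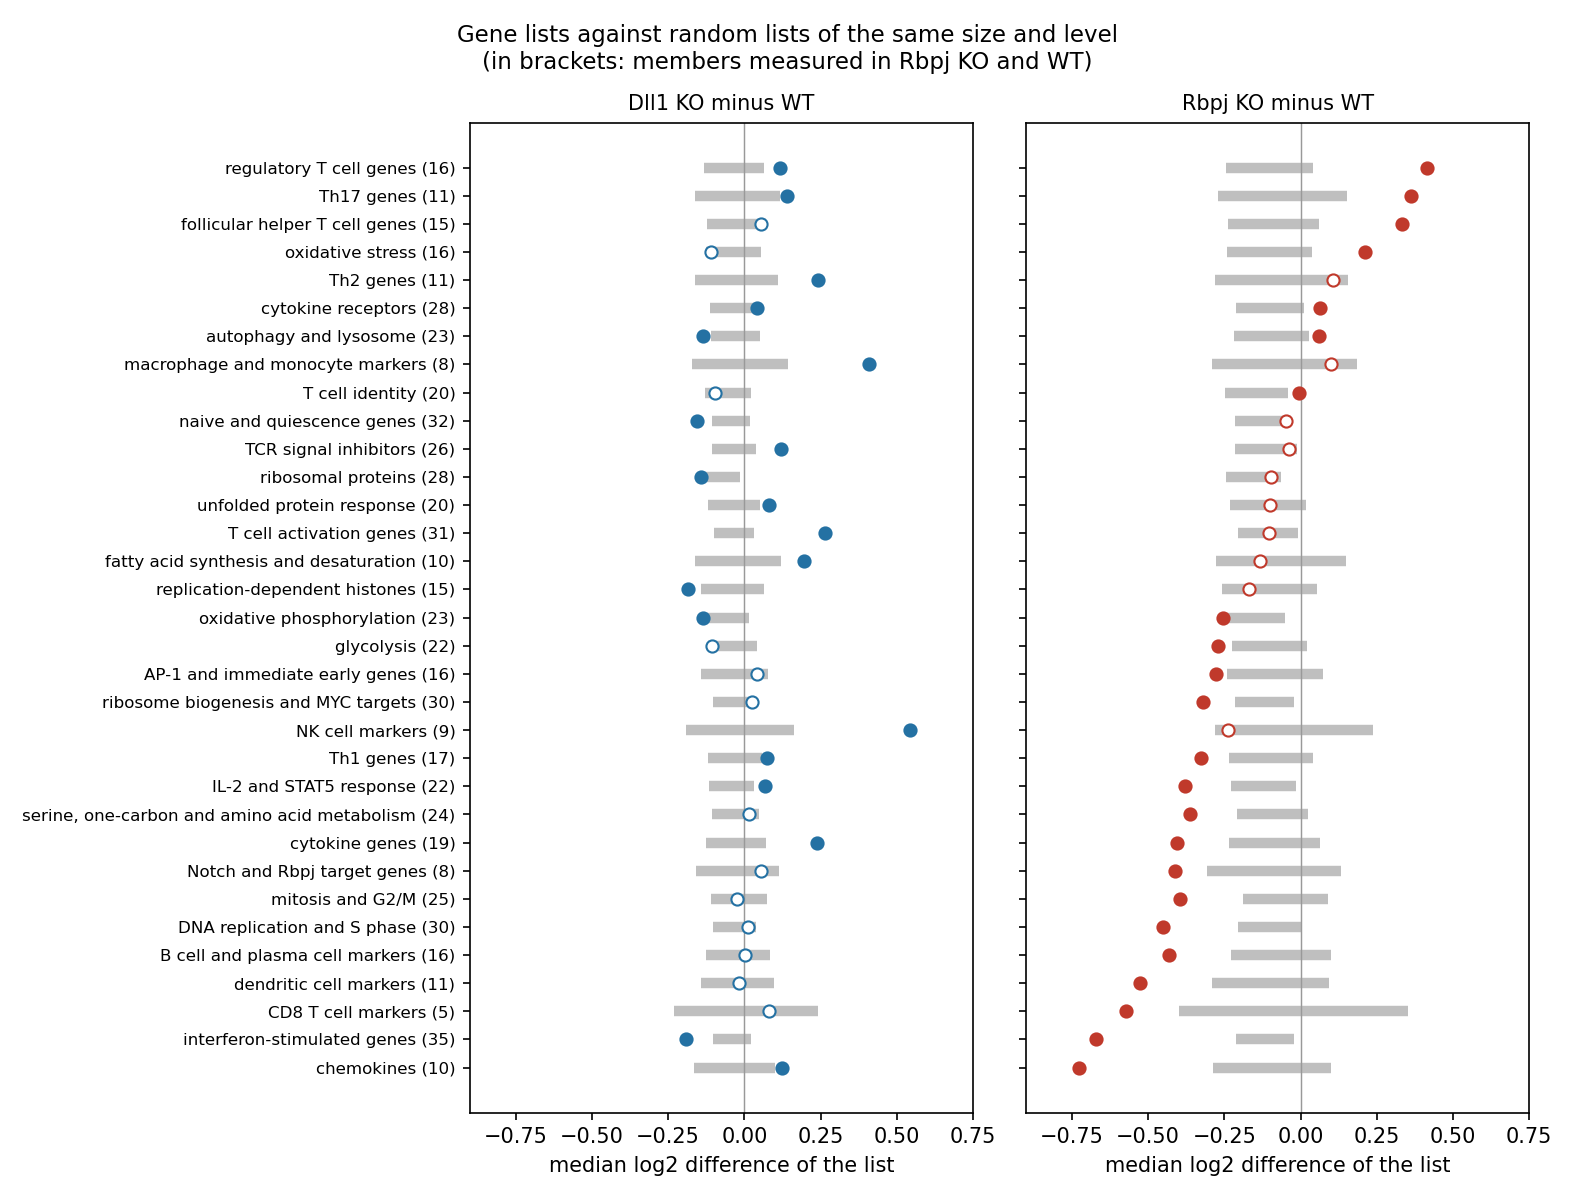
Median log2 difference of each gene list (x axis) in the Dll1 KO (left) and the Rbpj KO (right) against WT, with grey bars for the central 95% of 10000 random lists and filled points for lists outside them. In the Rbpj KO chemokines lie lowest at -0.73 and regulatory T cell genes highest at 0.41, a list that turns to -0.33 under spike-in scaling.

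Among 11578 genes measured in both, 160 were at least 2-fold higher and 249 at least 2-fold lower in the Rbpj KO (3.53%), and 88.2% were within 1.5-fold. Esm1, which encodes the secreted proteoglycan endocan, was highest at 22.0-fold. Lalba, a milk protein gene, was 8.42-fold higher, Pstpip2, an adaptor in inflammatory signalling, 5.28-fold higher, and Prg4, a lubricating proteoglycan, stood at a log2 difference of 2.07. In rows 1 to 192 lay Chil6, a chitinase-like gene, at 8.77-fold, Cpne7, a membrane-binding copine, at 6.56-fold and the lysosomal protease gene Lgmn at 4.10-fold higher. Pros1, an anticoagulant and ligand of TAM receptors, was 6.79-fold lower. The other 11 of the largest lower genes had their probes in rows 1 to 192, including the homeobox gene En2 at 10.8-fold, Gzma, Il4, the antigen-loading gene H2-DMa at 6.21-fold and Dtx1. Fbxo44, 5.28-fold lower as a mean of 2 probes, was at 0.01 log2 by its probe well above background on both arrays. Bounds numbered 122 at least 2-fold higher and 169 at least 2-fold lower, led by Olfr550 at least 11.6-fold higher and Olfr1311 at least 10.9-fold lower, both in rows 1 to 192.

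The count of 409 genes was 181 of 6685 with spots in rows 193 to 384 alone, 108 after normexp with quantile normalization and 2909 under spike-in scaling, of which 2883 were lower. In those rows alone the IL-2 and STAT5 list was no longer outside the random range (percentile 8.40), while too few Notch targets, Th17 and CD8 genes were left to be scored.

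Both knockouts share the WT array. Of 11542 genes measured on all 3 arrays, 43 were at least 2-fold lower and 12 at least 2-fold higher in both knockouts, and 1 was opposite. Among the 12 were the peptide transporter gene Slc15a2 and Klrg1. Independent lists of these sizes would share 1.47 lower and 0.54 higher genes, and 3 unchanged arrays in simulation shared on average 18.0 and 18.1. Of the 43 lower genes, 34 had all probes in rows 1 to 192 and 0 had all probes in rows 193 to 384. Across genes, which are not independent replicates, the differences had r = 0.31 against a simulated 0.50, and a covariance of 0.0353 against 0.0381, a difference of -0.00276. The WT array cannot be split, so part of any overlap may stem from it. In rows 193 to 384 alone, 2 genes were higher and 0 lower in both, so the excess of lower genes was not seen there. After normexp with quantile normalization 1 was higher and 0 lower. The normexp offset draws folds toward 1, so that count cannot show whether an excess remains.

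**Figure D4:**
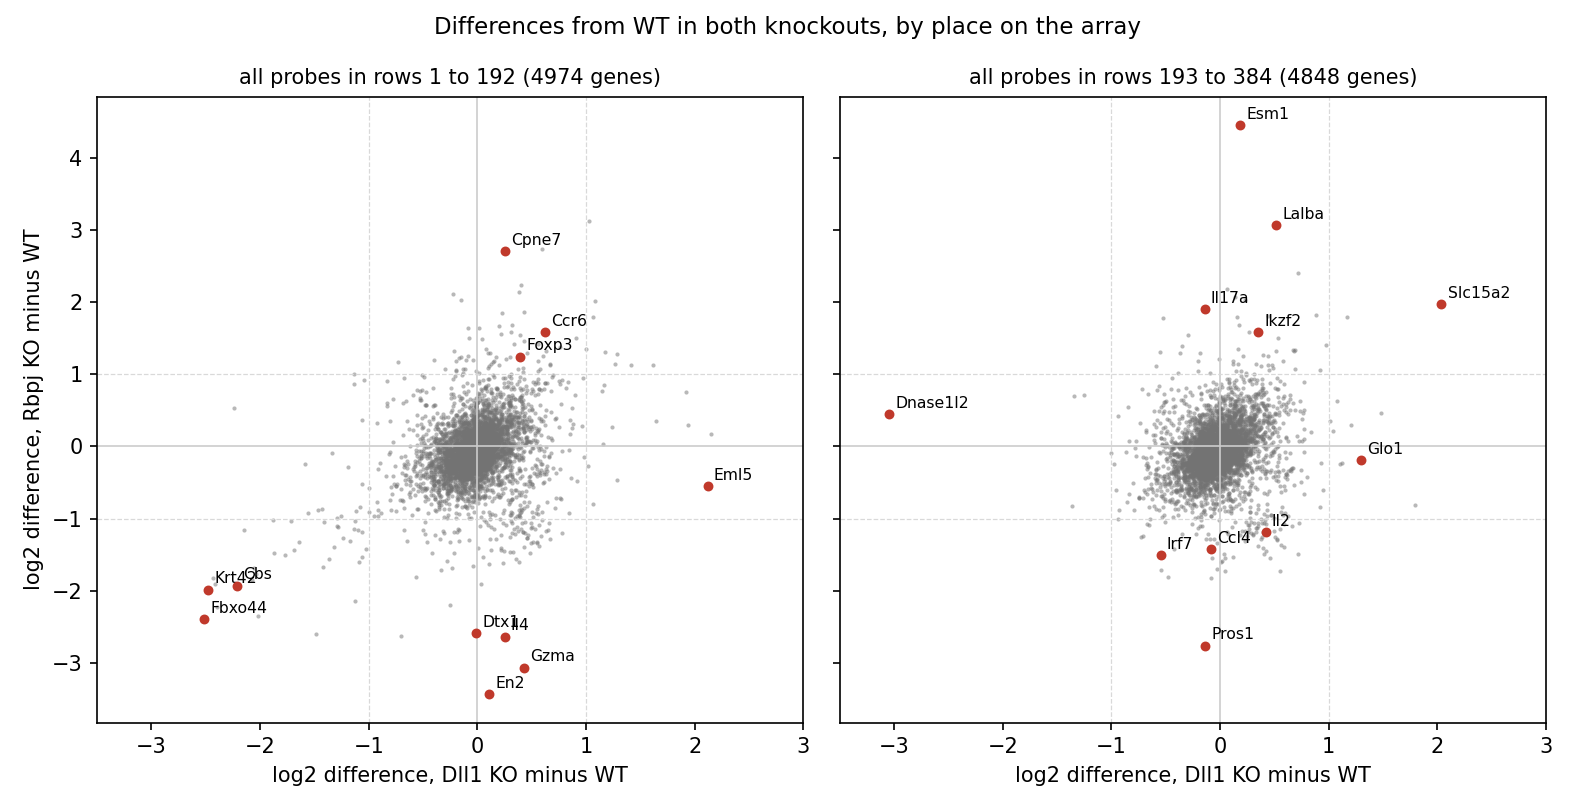
Log2 difference from WT in the Dll1 KO (x axis) and in the Rbpj KO (y axis), 1 point per gene, for genes with all probes in rows 1 to 192 (left) and in rows 193 to 384 (right), with dashed lines at 2-fold. The 34 genes lower in both knockouts with probes on one side lie in the left panel, and 0 lie in the right.

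The direct comparison of the knockouts asks how loss of Rbpj differs from loss of the ligand. Cytokine genes were lower in the Rbpj KO than in the Dll1 KO, with a median of -0.49 and Il4 at 7.41-fold, Csf2 at 3.86-fold and Il2 at 3.05-fold lower. Il3, a growth factor of myeloid progenitors, was at least 6.56-fold lower. Chemokine genes had a median of -1.21 with 11 of 11 lower, and T cell activation genes one of -0.40 with 24 of 31 lower. Regulatory T cell genes had a median of 0.41 with 13 of 17 higher, which turns to -0.12 under spike-in scaling. Dtx1 was 5.95-fold lower, and the granule protease gene Gzma 11.3-fold lower, while the cytotoxic gene list stayed inside the random range with a median of -0.18, at percentile 2.71.

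NK cell markers had a median of -1.01 over 10 genes, with Tyrobp 2.54-fold lower and Klra8, one of a family of similar receptors, 3.52-fold lower. Th1 genes had a median of -0.58 and included Tbx21, the T-bet gene, at 2.43-fold lower. Interferon-stimulated genes had a median of -0.50 with 33 of 35 lower. Of the S phase genes 30 of 30 were lower, with a median of -0.43, and ribosome biogenesis genes had a median of -0.38. Notch targets had a median of -0.50 over 8 genes, but one of 0.34 when dim probes were kept. S100a8 and S100a9 were 4.12-fold and 3.99-fold higher, which spike-in scaling does not reverse. Dim levels enter some of these folds, with S100a8 at -3.27 in the Dll1 KO and Klra8 at -3.43 in the Rbpj KO. After normexp with quantile normalization S100a8 and S100a9 were 1.68-fold and 2.60-fold higher, and Klra8 was 1.47-fold lower.

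Of 11794 genes, 183 were at least 2-fold higher and 308 at least 2-fold lower in the Rbpj KO than in the Dll1 KO (4.16%). Esm1 was 19.4-fold higher and Dnase1l2 11.3-fold higher, the latter being the gene 8.25-fold lower in the Dll1 KO than in WT. En2, with its probe in rows 1 to 192, was 11.7-fold lower. Pros1 at 6.18-fold and Fgd2 at 6.09-fold lower had theirs in rows 193 to 384, as had Esm1 and Dnase1l2. Of the 16 largest by the naming rule, 10 had their probes in rows 1 to 192 and 6 in rows 193 to 384. Bounds numbered 139 higher and 98 lower. The count of 491 was 240 of 6822 in rows 193 to 384 alone, 193 after normexp with quantile normalization and 1116 under spike-in scaling, where the median gene was at -0.56, against -0.03 in the main values and -0.15 under median scaling.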

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

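The test of clustering on the WT array and that of other probes of the same genes were set out before their results were seen, and the remaining tests here, like the split by rows, were chosen afterwards.

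More genes were lower than higher in both knockouts, 43 against 12. Chance values of the shared WT array stay open, since the simulation cannot decide. In the main values 3 unchanged arrays gave at most 26 such genes in 100 simulations. The noise was drawn from the Dll1 KO minus WT differences, which hold the pattern itself. Other settings were not simulated. The lower count there was 27 with the brightest probe, 28 with the filter on all 3 arrays, 43 under quantile normalization and 358 without a filter. It was 2 under the level filter and 0 under normexp, whose offset draws folds toward 1. The spots of the 43 genes lay close together on the array, with a median distance of 10.4 spots to the nearest other over 44 spots, against 18.5 for random spots (13.6 to 23.6 in 95% of sets). Other probes were compared for all genes with at least 2 probes well above background on all 3 arrays, not for the 43 genes alone. Where 1 probe read high on the WT array alone, 0 of 20 other probes of the same 14 genes were at least 1.5-fold higher there. For probes low in the Rbpj KO alone 25 of 60 (41.7%) agreed, over 41 genes. A local fault of the WT array, with single spots reading too high, is a candidate explanation. Probes high on 1 array alone were more frequent in rows 1 to 192 on the other arrays too. They numbered 455 against 68 in the Dll1 KO and 495 against 277 in the Rbpj KO. The distance was taken for the WT array only. Random spots came from the whole array, so crowding into those rows shortens it. The distance therefore cannot show a fault particular to the WT array. A shared change in both knockouts as the cause of the whole pattern is argued against by place. Of the 43 genes 0 had all probes in rows 193 to 384. The 0 of 20 other probes argue against a shared change for those 14 genes only. The upper 95% limit of their agreement, 16.8%, counts probes of one gene as independent. A shared change stays open for single genes.

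DNA replication and ribosome biogenesis genes were lower in the Rbpj KO. A trend with signal level is argued against, because after quantile normalization the S phase list still lay -0.34 log2 from random lists of its level, at percentile 0, and the ribosome biogenesis list -0.18. A lower share of stimulated cells stays open, because T cell activation genes as a list stood at percentile 50.7 of random lists with members going both ways, while immediate early genes (-0.28, percentile 0.79), IL-2 and STAT5 response genes (-0.38) and cytokine genes (-0.41) were lower. The immediate early list was inside the random range in rows 193 to 384 (percentile 11.2), under the level filter (20.45) and without a filter (6.1). An effect of Rbpj loss on these genes stays open and untested.

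Regulatory T cell genes were higher in the Rbpj KO. Replacement of conventional helper cells by B, dendritic, NK and CD8 T cells would raise the markers of those cells. Yet 3 of these 4 lists lay below random lists, though the dendritic list did not without a filter (median 0.06). These lists cannot speak to a smaller conventional share matched by a larger regulatory share. A larger share of regulatory T cells cannot be told apart from higher expression per cell, because each array measured the RNA of all cells together. Of the 16 measured genes 13 (81.2%) were above WT, short of nearly all, and Entpd1 at -1.21 ran the other way. No share of genes above WT could decide between them. An effect of the genotype on this list stays open and untested.

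Several lists lay on opposite sides of WT in the knockouts, beyond random lists in both and in the direct comparison of the knockouts. The direct comparison uses the same arrays and largely follows from the comparisons with WT, so it adds no independent support. Over mice the difference was not tested, with 1 array per group. The Th1 list had medians of 0.07 in the Dll1 KO (-0.14 under spike-in scaling, and percentile 93.6 in rows 193 to 384) and -0.33 in the Rbpj KO, with -0.58 between the knockouts. The IL-2 and STAT5 list had medians of 0.07 (-0.15 under spike-in scaling) and -0.38, with -0.27 between the knockouts, but in rows 193 to 384 the latter pair lay inside the random range, at percentiles 8.40 and 14.1. The cytokine list had medians of 0.24 and -0.41, with -0.49 between the knockouts. The chemokine list had medians of 0.12 (-0.09 under spike-in scaling, and -0.08 without a filter) and -0.73, with -1.21 between the knockouts. In the Dll1 KO against WT the chemokine list lay inside the random range without a filter (percentile 76.1). It was also inside, at the upper edge, in rows 193 to 384. The autophagy and lysosome list had medians of -0.14 (-0.02 and percentile 28.9 under normexp, and percentiles 14.4, 5 and 4.4 under the level filter, in rows 193 to 384 and with the brightest probe) and 0.06 (-0.69 under spike-in scaling, -0.11 under median scaling, and percentile 84.2 with the brightest probe), with 0.14 between the knockouts (-0.39 under spike-in scaling).

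The E1A spike-in spots, control RNA outside the gene comparisons, read higher in both knockouts after scaling. The median over 8 spike-in probes was 0.21 log2 above WT in the Dll1 KO (-0.15 to 0.25), with 7 of 8 higher. In the Rbpj KO it was 0.74 above WT (-0.63 to 0.81), again with 7 of 8 higher. A pair of ERCC control probes well above background on every spot went the other way in the Rbpj KO, at -1.20 and -1.16, and stood at 0.45 and 0.45 in the Dll1 KO. Whether ERCC RNA was added is not given in the sources used here. Most other ERCC probes read near the floor on every array. The probe for ERCC-00002, for example, stood at -5.30 in WT, -5.73 in the Dll1 KO and -5.28 in the Rbpj KO. These values argue against an added ERCC mix, so the bright pair is no check on the E1A spots.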

How the results depend on the processing

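Spike-in scaling, the level filter, the filter of probes by pair and the choice of rows were added after the data were seen. No paired analysis was possible because each group has 1 array and all carry replicate number 1, and leaving out an array could not be done. Slide and scan time could not be tested, as all 3 arrays lie on 1 slide with 1 scan time. Leaving out saturated probes removed nothing and says nothing about stability. Quantile normalization, the series values and median scaling kept each count within 1.5 times. The split of higher against lower moved under median scaling, from 39.1% to 21.8% higher in the Rbpj KO against WT and from 37.3% to 25.8% between the knockouts.

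Counts of genes at least 2-fold apart are given for the Dll1 KO against WT, the Rbpj KO against WT, the knockouts and both knockouts together, where the main values were 132, 409, 491 and 55. Normexp with quantile normalization gave 11 (54.5% higher, against 33.3%), 108, 193 and 1. Without a filter on dim probes they were 1147 (46.0% higher), 1753 (56.6%, against 39.1%), 1936 (59.4%, against 37.3%) and 506, so that higher genes outnumbered lower ones in the comparisons with the Rbpj KO. A filter on all 3 arrays gave 67 for the Dll1 KO and 36 for both together, and the brightest probe gave 88 and 37. A level of at least the 75th percentile gave 8 (4 higher and 4 lower), 124 (17.7% higher), 178 (20.8%) and 2. Rows 193 to 384 gave 17 (70.6% higher), 181, 240 and 2, with fewer genes measured. Spike-in scaling gave 159 (15.1% higher), 2909 (0.894%) and 1116 (4.57%), by its shift of all genes. At 1.5-fold the counts were 496, 1363 and 1366, and at 3-fold 42, 87 and 137. Where fewer genes were not the reason the cause was not tested.

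Of 74 calls on lists, 70 held under quantile normalization, 66 under normexp, 66 with the brightest probe, 67 without a filter, 73 with the filter on all 3 arrays, 64 of 71 under the level filter and 46 of 67 in rows 193 to 384. Distances from random lists changed sign in 5 cases, the cause not being tested. Without a filter these were -0.10 for macrophage markers in the Dll1 KO, 0.0257 for Notch targets and 0.0932 for dendritic markers in the Rbpj KO, and 0.19 for Notch targets between the knockouts. In rows 193 to 384 heat shock genes between the knockouts were at 0.000405. Among named genes Fbxo44 became 0.60 in the Dll1 KO and 0.0101 in the Rbpj KO, and Trank1 0.14 in the Dll1 KO, under the filter on all 3 arrays, the brightest probe and the probe filter by pair, since their dim probes are left out. Under normexp with quantile normalization 261 of 317 named values moved, as its offset draws folds toward 1 by construction, and in the Rbpj KO Esm1 was 8.62-fold and Il17a 1.90-fold higher, and En2 3.55-fold, Gzma 4.73-fold, Il4 4.10-fold and Dtx1 3.32-fold lower. Signal over background limits the dim genes most. Of the 44 higher and 88 lower genes of the Dll1 KO, 26 and 63 were among 1549 genes below -2 log2 on the dimmer array. A gene can enter that group through its difference alone, so these shares do not show that the genes were dim on both arrays.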

Other observations

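No test was run for this part, and its lists were fixed before the data were examined. Some lists of metabolic genes lay apart from random lists, which 1 array per group cannot tie to genotype. The cholesterol and fatty acid lists did not in the Rbpj KO against WT, at percentiles 7.13 and 27.8. In the Rbpj KO genes of serine, one-carbon and amino acid metabolism had a median of -0.36 against WT with 20 of 24 lower, led by the stress factor gene Atf3 at 3.33-fold lower. Glycolysis genes had a median of -0.27 with 17 of 22 lower, at percentile 0.41 of random lists, although the glucose transporter gene Slc2a3 was at 0.64, or -0.11 under spike-in scaling. The oxidative phosphorylation list had a median of -0.25 with 23 of 23 lower, but lay inside the random range under quantile normalization (percentile 9.60), normexp (4.4), the brightest probe (5.70) and rows 193 to 384 (4.15), as did the glycolysis list under quantile normalization (3.60). The oxidative phosphorylation list was below random lists in the Dll1 KO against WT too, with a median of -0.14 and 21 of 23 lower. It was not apart between the knockouts, at percentile 53.9. In the Dll1 KO genes of fatty acid synthesis had a median of 0.19, led by the synthase gene Fasn at 0.50, and fell inside the random range under the level filter (percentile 97.0), while under spike-in scaling the median was -0.02. Between the knockouts that list had a median of -0.38 with 9 of 10 lower in the Rbpj KO.

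Receptors for inhibition and homing differed by single genes without a shift of their lists. Tigit, an inhibitory receptor of regulatory and exhausted T cells, stood at 0.90 in the Dll1 KO and 1.51 in the Rbpj KO against WT, with its probe in rows 1 to 192. Cd160, a receptor of killer cells, stood at -0.48 and -1.80. Itga4, a chain of the homing integrin VLA-4, was 2.06-fold higher in the Rbpj KO. Cdkn1a, the p21 inhibitor of cell division, was 2.30-fold lower in the Rbpj KO as a mean of 2 probes, with -0.66 for the probe well above background on both arrays. Replication-dependent histone genes had a median of -0.18 in the Dll1 KO with 14 of 16 lower, though their probes can pick up related copies.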
